A study of Mus musculus with 16 samples.

How the data were processed

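The samples were 16 RNA sequencing libraries from the duodenal epithelium of mice, 1 library per sample. Per the labels, 9 mice carried Ephb4 alleles flanked by recombination sites (flox, replicates 1 to 7, 9 and 10), and 7 lacked Ephb4 in the intestinal epithelium (KO, replicates 1 to 5, 7 and 8). All were 8 weeks old at the start and ate a high fat diet for 19 weeks. The labels call the sample duodenal epithelium, while the design text calls it tissue of the proximal small intestine. The recombinase line is not given in the sources used here. Per the labels' protocols, RNA was extracted with TRIzol, messenger RNA was taken with poly-T beads, and libraries were made with the NEBNext Ultra RNA kit.

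Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 were used with the GRCm38 (mm10) mouse genome. Their settings are not given in the sources used here. The one deposited table held 2438 genes, and its largest adjusted p was 0.0497, so it held only genes that the authors had selected as different between these same libraries. From the deposited p-values and their adjusted values, the authors' Benjamini-Hochberg adjustment ran over 16488 genes. The other genes were not analysed here, so a gene that was not listed may have missed the threshold or may not have been tested. The deposited table also gave the authors' log2 fold change of KO over flox for each gene.

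The signal in the deposited library columns was a read count divided by 1 size factor per library, as the values themselves showed. In each library, 100% of the nonzero values were whole multiples of 1 step within a tolerance of 0.0001 reads. The size factors recovered from these steps ran from 0.878 to 1.38. An automatic check of this recovery could not test KO replicates 1 and 3. KO replicate 1 had few low values, and in KO replicate 3 a read was worth 1.01, too close to 1 to be told from unscaled counts. Count models on recovered reads were therefore run on all 16 libraries and again without these 2. The recovered reads in the listed genes ran from 3592468 to 5316273 per library. These are not library totals, since reads in unlisted genes were not used here, and the total depth is unknown. All values below are in these normalised counts, given as mean ± SD with the number of libraries. No column of other samples was present. No 2 libraries of a group were duplicates, since the smallest chi-square per degree of freedom between recovered reads was 16.7. The labels do not state whether each library came from its own mouse, but the numbers of libraries equal the numbers of mice in the design text.

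Before the data were examined, the groups, the design, the settings to be varied, 42 gene lists and the rule for named genes were fixed. Because the genes had been selected on these libraries, the adjusted p of the comparison is that of the authors, as fixed beforehand for this case, and no test of enrichment was run for the 42 lists. Fisher's exact tests among the listed genes, for 9 gene families and 20 chromosomes, were added after the data were seen. An own fit checked the fold changes. limma 3.58.1 was run with a mean-variance trend and robust moderation on log2(normalised count + 1) for the 2339 listed genes with a mean of at least 10. Its two-sided p-values were adjusted by the Benjamini-Hochberg method over 16488 genes with every unlisted gene set to a p of 1, which is conservative. A fold change on this scale understates the change of genes with low counts. Genes are called changed at an adjusted p under 0.05. Counts at an unadjusted p under 0.05 in limma are also given below. Listed genes had already passed the authors' adjusted threshold on these libraries. With all 16 libraries these unadjusted counts were therefore largely fixed in advance and add no separate support. Single values such as Ephb4 and the scores per library were compared by two-sided exact permutation tests over all 11440 splits of the 16 libraries into groups of 9 and 7. No batch was given in the labels. The libraries were numbered within each group, and 6 numbers occurred in both groups.

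Counts were simulated from the real means and library sizes, with 200 of 2339 genes changed. On these limma recovered 49.3% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 98.5% of those changed 4-fold. It called 0% of unchanged genes. Each gene was drawn independently, without the variation that genes share in the real libraries, so these rates may not hold there. edgeR 4.0.16 and DESeq2 1.42.0 were tested in the same way and then run on the recovered reads. The submitters' notes name DESeq2 for their own analysis, and the run here used the recovered size factors. It called 2233 of the 2438 listed genes. Its counts below therefore nearly repeat the authors' selection and add no separate support.

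The genes named below are Ephb4, the 10 genes with the largest rise and the 10 with the largest fall in the authors' log2 fold change among listed genes with a mean of at least 50, without predicted genes, pseudogenes and immune receptor segments, and up to 4 members of each gene list with the smallest adjusted p. A few genes that this rule selects are not reported here. Other genes were chosen after their values were seen, and this is said where they appear. For each list the number of listed members is given, in each direction, with the number that passed when the authors' p-values were adjusted over the list alone and unlisted members were set to a p of 1. Listed genes had already passed the authors' threshold, so this second count was fixed in advance where at least 14.8% of a list was listed. It equalled the listed count in every list and adds no further support.

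A non-epithelial score per library was the mean, over the 13 listed markers of T and innate lymphocytes, B and plasma cells, mast cells, fibroblasts and endothelium, of the log2 value centred on the gene's mean. A pancreatic score used the 10 listed members of the stomach and pancreas list in the same way. These markers were themselves listed as different between the groups. Gene coordinates are those of the deposited table. Of the 2438 gene identifiers, 2335 had the same coordinates in the GRCm38 annotation used here, and the GC content of the longest annotated transcript was taken for 2437.

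The other settings chosen beforehand were DESeq2 on recovered reads, TMM scaling and quantile normalisation, other filters and pseudocounts (0.5 and 5), a fold threshold, the replicate number as a block and each library left out in turn. TMM scaling and quantile normalisation assume that most genes are unchanged, but here they could use only genes selected as changed. Chosen after seeing the data were edgeR on recovered reads, both count models without KO replicates 1 and 3, the non-epithelial and the pancreatic score as covariates, leaving out 5 flox libraries with pancreatic transcripts, and removal of a quadratic trend with GC content per library, without or with the library mean kept, of which the list scores used the latter. The exact binomial interval of a ratio of reads covers counting error only. Calculations used R 4.3.3, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and the plots were drawn with matplotlib 3.10.9.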

Results

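The data were normalised read counts of 2438 genes in the duodenal epithelium of mice on a high fat diet, from 9 mice with floxed Ephb4 and 7 mice without Ephb4 in the intestinal epithelium. The comparison asked which transcripts of the proximal small intestine differ when the epithelium lacks EphB4, a receptor tyrosine kinase whose ligand is ephrin-B2, during diet-induced obesity. Reads in the listed genes ranged from 4237178 to 5316273 in the flox libraries and from 3592468 to 4555872 in the KO libraries.

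Ephb4 (5:137350109 to 137378669, GRCm38, plus strand, ENSMUSG00000029710) was 5.76-fold lower in KO, at 36.6 ± 21.7 normalised counts (SD, n = 7) against 210.5 ± 94.4 in flox (SD, n = 9). The groups did not overlap. Its log2 difference was -2.51 with an exact permutation p of 8.74e-05, the smallest that 11440 splits can give (two-sided). The authors' deposited table gave a log2 fold change of -2.52 and an adjusted p of 1.03e-13. KO replicate 1 held 84.7 normalised counts, more than any other KO library and less than the lowest flox library at 103. Reads from exons outside the deleted part and from other cells are counted too, so the remaining reads do not measure intact transcript.

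In the KO epithelium, 15 of 25 genes for fat uptake, 11 of 30 for fat oxidation and 8 of 15 markers of mature enterocytes fell, and 14 of 25 proliferation genes rose. Of 80 markers of lymphocytes, mast cells, stroma and endothelium 13 were listed (16.3%), all of them higher. Of all 16488 genes adjusted over, 14.8% were listed in either direction, and 1150 were listed as higher. Direction went with abundance among all listed genes. At a mean of at least 1000 normalised counts 712 were lower and 56 higher, and at 200 to 1000 448 were lower and 231 higher. At 50 to 200 82 were lower and 427 higher, and under 50 46 were lower and 436 higher. Whether the lists differ from other listed genes of like abundance was not tested. Most falls were modest, with a median log2 fold change of -0.37 over the lower genes and 0.75 over the higher genes in the authors' deposited table. Of the 2438 genes in the authors' deposited table, 1150 were higher and 1288 lower in KO, which is 14.8% of the 16488 genes adjusted over. Only 372 of the higher and 65 of the lower genes reached an absolute log2 fold change of 1 in the authors' deposited table. In the own limma check, 1269 of the listed genes passed, 449 higher and 820 lower. With TMM scaling on the listed genes, which moved the median log2 difference by 0.14, that split became 723 higher and 189 lower. The number passing limma fell to 11 when 5 flox libraries that held pancreatic transcripts were left out and to 7 when the non-epithelial marker score was a covariate, both chosen after seeing the data. Of the single libraries, KO replicates 1, 5 and 7 and flox replicates 3, 4 and 10 each moved the count by over 1.5 times when left out, to 645, 622, 518, 615, 838 and 646.

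**Figure D1:**
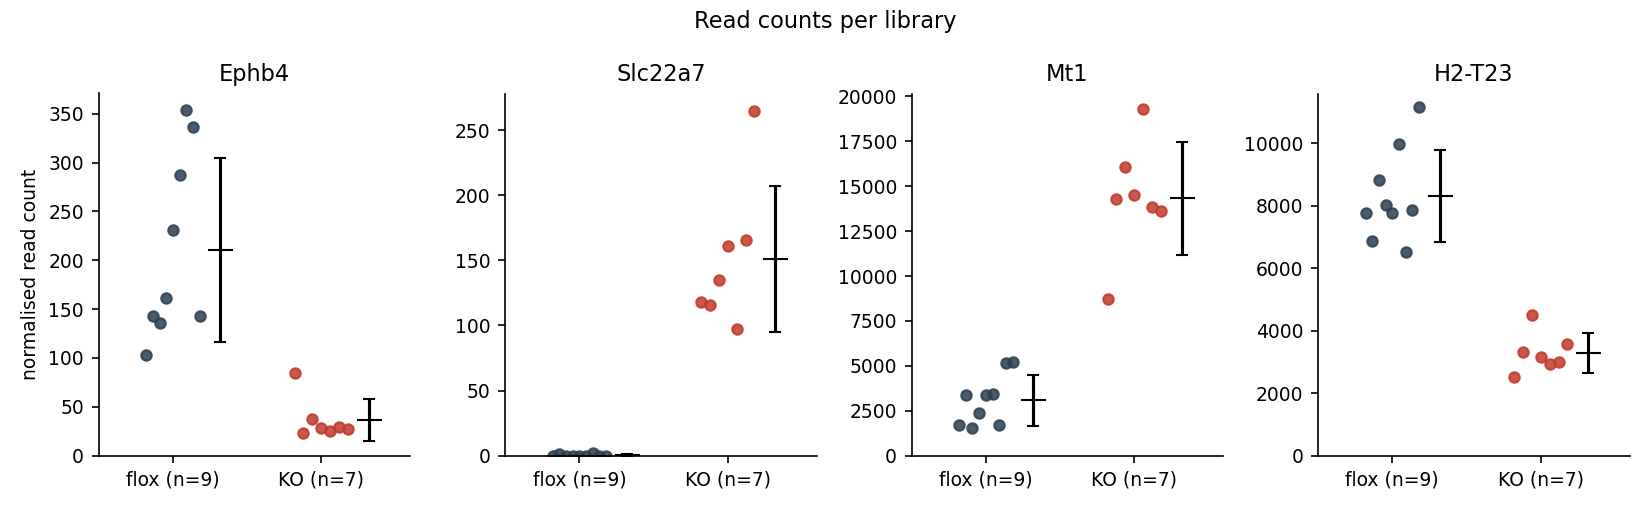
Normalised read counts (linear axes) of Ephb4, Slc22a7, Mt1 and H2-T23 in each of 9 flox and 7 KO libraries, with the group mean and SD as the bar beside the points. In all 4 genes the flox and KO libraries do not overlap, and Ephb4 in KO replicate 1 lies at 84.7, above the other KO libraries.

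Some genes of dietary fat handling fell. Of 25 genes of fat uptake and chylomicron assembly, 15 were listed, all of them lower in KO. Adjusted over the list alone 15 were lower, a count that the listing had fixed. Fabp1, the liver-type fatty acid binding protein that is abundant in duodenal enterocytes, fell from 72989 ± 17147 (SD, n = 9) to 37360 ± 14328 normalised counts (SD, n = 7). Cideb, a lipid droplet protein involved in lipoprotein lipidation, fell by 0.67 ± 0.09 (SE) on the log2 scale, with an adjusted p of 0.00117 in limma. Slc27a4, a fatty acid transport protein, fell 1.53-fold and the lipid droplet coat protein Plin3 fell 1.42-fold. Of the 15 members, 10 passed the limma check, 7 did so without KO replicate 1, and 0 did so with the non-epithelial score as a covariate or without the 5 flox libraries with pancreatic transcripts. At an unadjusted p under 0.05 in limma these last counts were 6 and 15. On all recovered reads edgeR and DESeq2 called 10 and 15. Here and below, neither the unadjusted counts nor the DESeq2 counts are separate support, since the genes were selected on these libraries. The median log2 difference of the 15 was -0.48 in limma, -0.33 with that covariate and -0.46 without those libraries. It was -0.30 with the GC trend removed and library means kept, where 6 passed. With quantile normalisation over the listed genes the median was -0.09 and 6 members changed sign. Of the listed genes with a mean of at least 1000, 712 were lower and 56 higher in KO. Giving all libraries the same distribution over such genes reduces their fall by construction. Sign changes with this method, here and below, therefore cannot show that a fall is unreal.

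Some fatty acid oxidation genes fell. Of 30 genes of fatty acid oxidation and ketogenesis, 11 were listed, all lower, and 11 were lower when adjusted over the list alone. Acadvl, the very long chain acyl-CoA dehydrogenase of mitochondria, fell from 2484 ± 204 (SD, n = 9) to 1772 ± 167 (SD, n = 7). The peroxisomal enzyme Acaa1a fell 1.49-fold. In limma 8 of the 11 passed, 5 did so without KO replicate 1, and 0 did so with the covariate or without the flox libraries with pancreatic transcripts. At an unadjusted p under 0.05 in limma these last counts were 4 and 10, and edgeR and DESeq2 on recovered reads called 8 and 11. The median log2 difference was -0.40 in limma, -0.28 with the covariate, -0.44 without those libraries and -0.07 with quantile normalisation, where 2 members changed sign. The non-epithelial score, which was higher in KO, is given below.

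Some markers of mature enterocytes fell. Of 15 such markers 8 were listed, all lower and all 8 when adjusted over the list alone, but 5 of the 8 stood on another list as well, 3 of them on that of fat uptake. Rbp2, a retinol binding protein, fell from 121874 ± 14022 (SD, n = 9) to 84520 ± 14903 (SD, n = 7), and the brush border protein Vil1 fell 1.26-fold. Among 12 genes of the villus tip, only Creb3l3, a transcription factor of lipid metabolism that is also on the fat uptake list, was listed, 1.38-fold lower and also the 1 gene adjusted over the list alone. In limma 6 of the 8 enterocyte markers passed, 3 without KO replicate 1 and 0 with the covariate, where 3 had an unadjusted p under 0.05, and edgeR and DESeq2 on recovered reads called 6 and 8. Quantile normalisation turned the sign of 4 of the 8.

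Some genes of nutrient transport and digestion fell. Of 17 genes of peptide and amino acid absorption 6 fell, with the transporters Slc7a8 and Slc7a7 1.45-fold and 1.29-fold lower. Slc43a2 fell 1.33-fold and the brush border protease Mep1a 1.43-fold. Of 15 genes of sugar digestion and absorption 4 fell, among them the disaccharidases Treh (1.37-fold) and Lct (1.35-fold), ketohexokinase Khk (1.33-fold) and Slc37a4 (1.22-fold). Of 25 xenobiotic and glutathione genes 3 fell, namely Cyp2d26, Ces2c and the nuclear receptor Nr1i2 (1.38-fold). Adjusted over the list alone, the counts lower were again 6, 4 and 3. In limma 3, 2 and 2 of them passed, and 0 in each list with the non-epithelial score as a covariate, where 0, 1 and 0 had an unadjusted p under 0.05. On recovered reads edgeR called 3, 2 and 3 and DESeq2 6, 4 and 3. With quantile normalisation 1 of the 4 sugar genes changed sign. Once the GC trend was removed 3, 0 and 1 passed limma, and 6, 2 and 3 had an unadjusted p under 0.05. With library means kept 1, 0 and 1 passed, and again 6, 2 and 3 had an unadjusted p under 0.05.

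Of 23 genes of oxidative phosphorylation 5 fell, with Atp5o 1.35-fold, Ndufb8 1.40-fold, Ndufv1 1.32-fold and Sdha 1.17-fold lower, and 5 were lower adjusted over the list alone. None of the 13 mitochondrially encoded transcripts was listed. In limma 3 of the 5 passed, 1 did so without KO replicate 1, and 0 did so with the covariate or without the flox libraries with pancreatic transcripts. At an unadjusted p under 0.05 in limma these last counts were 0 and 1, and edgeR and DESeq2 on recovered reads called 3 and 5. Quantile normalisation turned the sign of 2, and with the covariate the median log2 difference was -0.09.

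Lipid synthesis genes were mixed. Of 25 genes of cholesterol synthesis and uptake 4 rose and 2 fell, and the same counts held when adjusted over the list alone. Idi1, an isomerase of the mevalonate pathway, rose from 210.7 ± 44.5 (SD, n = 9) to 334.9 ± 68.0 (SD, n = 7), and Sqle rose 1.33-fold. Tm7sf2 fell 1.24-fold. Of 19 genes of fatty acid and triglyceride synthesis 2 rose and 1 fell, also adjusted over the list alone. The desaturase Fads1 rose 1.84-fold and the elongase Elovl5 1.41-fold, and Agpat2 fell 1.33-fold. Of 15 genes of sterol efflux and bile acid handling 1 rose and 2 fell, the same adjusted over the list alone. These were Mylip (2.21-fold higher), the cholesterol esterifying enzyme Soat2 (1.41-fold lower) and the oxysterol receptor Nr1h3 (1.28-fold lower). Mylip had a log2 difference of -0.36 with the non-epithelial score as a covariate. Of these 12 listed genes, Idi1, Elovl5, Agpat2, Soat2 and Nr1h3 passed limma. After removal of the GC trend the median log2 differences of the 3 lists went from 0.40, 0.50 and -0.34 to 0.14, 0.07 and -0.16, and 2, 0 and 0 members passed limma, with 2, 1 and 2 at an unadjusted p under 0.05. With library means kept the medians were 0.28, 0.21 and -0.02. In that setting 1, 0 and 0 members passed limma, with 5, 1 and 2 at an unadjusted p under 0.05. With the non-epithelial covariate 0 members of each list passed limma, with 2, 0 and 0 at an unadjusted p under 0.05, and on recovered reads edgeR called 2, 2 and 2 and DESeq2 4, 3 and 3.

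The metal-binding protein Mt1 rose 4.63-fold, from 3093 ± 1414 (SD, n = 9) to 14331 ± 3151 (SD, n = 7), with an adjusted p of 0.000133 in limma. Of 14 genes of iron, calcium and mineral uptake 2 rose (Mt1 and the transferrin receptor Tfrc, 1.56-fold) and 2 fell (the zinc importer Slc39a4, 1.27-fold, and ferritin light chain Ftl1, 1.26-fold), and the same adjusted over the list alone. Mt2, the other metallothionein gene among the 14, was not listed, and why Mt1 rose was not tested. Mt1 also passed limma without the 5 flox libraries with pancreatic transcripts. With the covariate its log2 difference was 2.26 and its adjusted p in limma 0.126. Of the 4 listed genes Mt1 and Slc39a4 passed limma. With the non-epithelial covariate 0 passed and 1 had an unadjusted p under 0.05. On recovered reads edgeR called 1 of the 4 and DESeq2 called 2 higher and 2 lower.

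Some genes of proliferating cells rose. Of 25 proliferation genes 14 were listed, all higher, and all 14 when adjusted over the list alone. Mki67, a marker of cycling cells, rose from 402.3 ± 193 (SD, n = 9) to 803.3 ± 249 (SD, n = 7). The ribonucleotide reductase subunit Rrm1 rose 1.82-fold, the replication helicase subunit Mcm4 1.69-fold and the mitotic kinase Aurka 1.54-fold. In limma 8 of the 14 passed, 1 did so without KO replicate 1, and 0 did so with the covariate or without the flox libraries with pancreatic transcripts. At an unadjusted p under 0.05 in limma these last counts were 2 and 14, and edgeR and DESeq2 on recovered reads called 5 and 13. Their median log2 difference was 0.93, 0.82 without KO replicate 1, 0.64 with the covariate and 1.27 without those flox libraries. It was 0.56 once the GC trend was removed, or 0.70 with library means kept, and 1 or 2 of the 14 passed limma. None of the 14 intestinal stem cell markers was listed. Of 19 Wnt and Notch genes 1 rose and 1 fell, also adjusted over the list alone: Tcf7, which lymphocytes express as well, rose 2.30-fold, and Sp5 fell 1.52-fold. With the covariate the log2 difference of Tcf7 was -0.01.

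**Figure D2:**
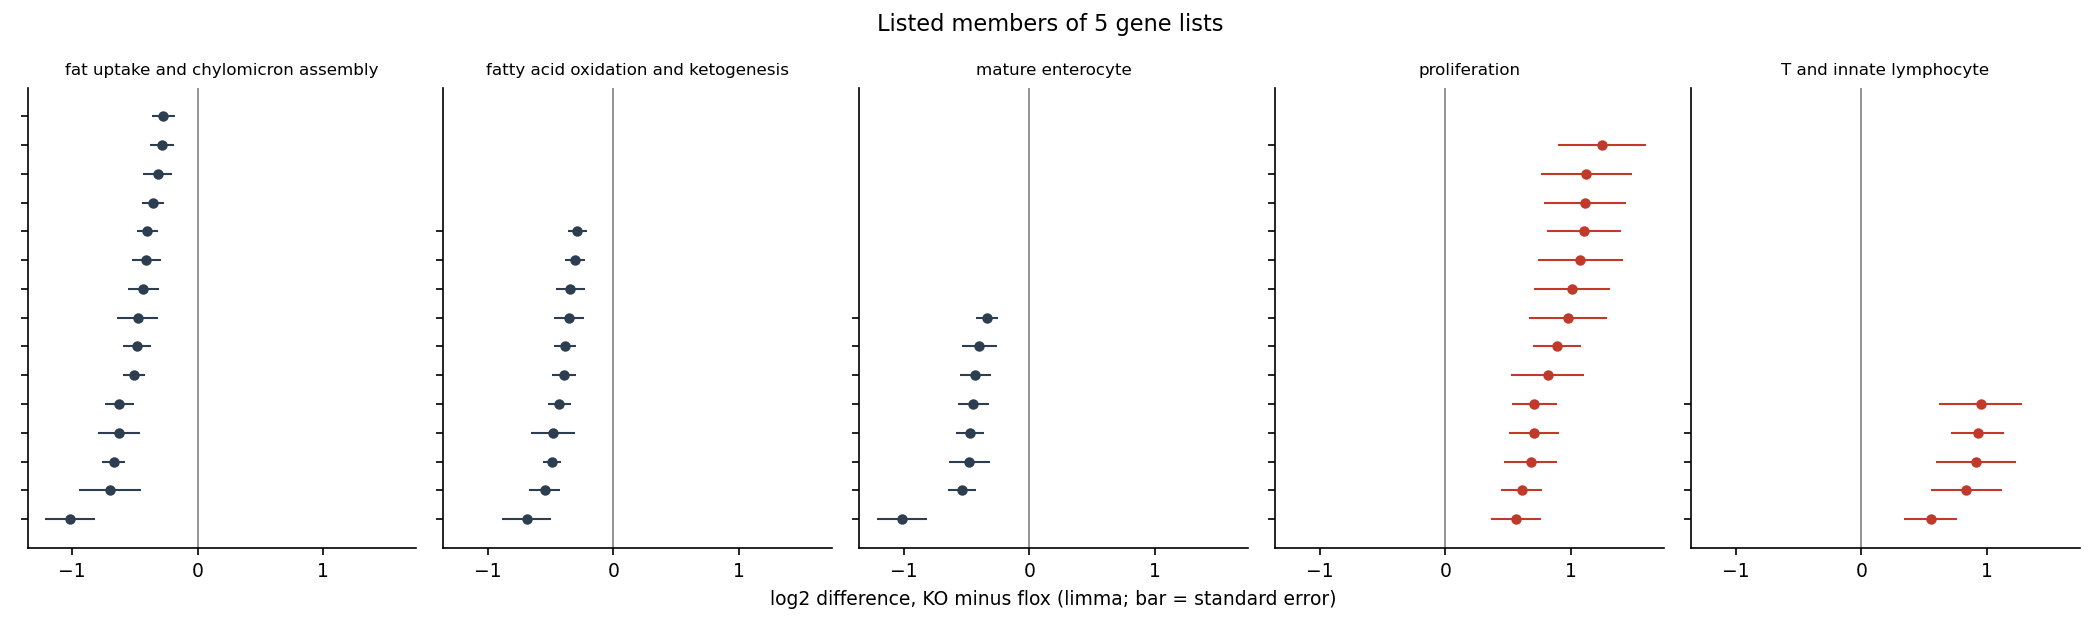
Log2 difference of KO minus flox (limma on log2 of normalised count + 1, 7 against 9 libraries) of the listed members of 5 gene lists, with the standard error as the bar. All 15 fat uptake, 11 fat oxidation and 8 enterocyte members lie below 0, and all 14 proliferation and 5 lymphocyte members lie above it. With quantile normalisation, which was run over selected genes only, 6, 2 and 4 members of the first 3 lists change sign.

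Some cell junction and Eph family genes fell. Of 19 tight and adherens junction genes 7 fell, and 7 adjusted over the list alone, with Cgn 1.24-fold, Cldn3 1.26-fold and F11r 1.19-fold lower. In limma 2 of these 7 passed, and 0 did so without KO replicate 1 or with the non-epithelial covariate, where 7 and 0 had an unadjusted p under 0.05. On recovered reads edgeR and DESeq2 called 2 and 7. The median log2 difference was -0.30 in limma and -0.09 with the covariate, and quantile normalisation turned the sign of all 7. It was -0.12 with the GC trend removed and library means kept, where 0 of the 7 passed as lower and 1 as higher, with 3 at an unadjusted p under 0.05. Of 19 Eph receptors and ephrins 3 fell, and 3 adjusted over the list alone, with Epha1 1.32-fold and Efnb1 1.36-fold lower beside Ephb4. With the non-epithelial score as a covariate only Ephb4 of these 3 passed limma.

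Of 23 enteroendocrine genes 5 fell, and 5 adjusted over the list alone. They included the granule proteins Chga (1.41-fold) and Chgb (1.39-fold) and the hormones Cck (1.37-fold) and Sct (1.55-fold). In limma 2 of the 5 passed, and 0 did so without KO replicate 1 or with the non-epithelial covariate, where 5 and 0 had an unadjusted p under 0.05. On recovered reads edgeR and DESeq2 called 3 and 5. The median log2 difference was -0.47 in limma, -0.18 with the covariate and -0.28 after removal of the GC trend, or -0.14 with library means kept. Of 14 goblet cell genes 2 fell, Fcgbp (1.30-fold) and Zg16 (1.23-fold), and quantile normalisation turned the sign of 1 of them. In limma 0 of these 2 passed and 2 had an unadjusted p under 0.05, and edgeR and DESeq2 on recovered reads called 0 and 2. Of 17 tuft cell genes 1 rose, Kctd12 (1.39-fold). Of 10 Brunner gland genes 1 fell, Cym (1.53-fold), and of 12 ileal and colonic genes 1 fell. None of the 13 Paneth cell genes was listed. Adjusted over the list alone, the goblet, tuft, Brunner gland and ileal counts were again 2, 1, 1 and 1.

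None of 10 MHC class II genes and none of 22 cytokine and chemokine genes was listed. Of 27 interferon response genes 1 fell, the immunoproteasome subunit Psmb8 (1.43-fold), and of 20 antimicrobial genes 1 fell, Reg3a (1.74-fold). Of 24 genes of the unfolded protein and integrated stress response 1 fell, Trib3 (1.28-fold). Each of these was also the 1 gene adjusted over the list alone. Trib3 passed limma, but not without KO replicate 1. Its log2 difference went from -0.37 to 0.04 with the GC trend removed and library means kept. Of 19 immediate early and heat shock genes, which also respond to tissue handling, 3 rose and 4 fell, the same adjusted over the list alone. Junb fell 1.45-fold, Zfp36 1.26-fold and Dnajb1 1.31-fold, while Hsp90aa1 rose 1.36-fold. In limma 4 of these 7 passed, and 0 did so with the non-epithelial covariate or after removal of the GC trend, where 4 and 4 had an unadjusted p under 0.05, and on recovered reads edgeR and DESeq2 called 4 and 6. Of 18 circadian clock genes Arntl rose 1.28-fold and Cry2 fell 1.36-fold, 1 each way also adjusted over the list alone. Psmb8, Reg3a, Arntl and Cry2 did not pass limma, and all 4 had an unadjusted p under 0.05. On recovered reads edgeR called only Psmb8 of the 4 and DESeq2 called all 4.

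Some markers of cells other than epithelium rose. Of 21 T and innate lymphocyte markers 5 rose, with Trbc2 1.89-fold, Cd4 2.15-fold, Ptprc 1.85-fold and Il7r 1.87-fold higher. Of 15 B and plasma cell markers 2 rose, Pou2af1 (3.61-fold) and Mzb1 (2.22-fold). Of 13 mast cell and eosinophil markers 2 rose, the mast cell proteases Mcpt1 (2.31-fold) and Mcpt2 (2.35-fold). Of 16 fibroblast and matrix markers 3 rose, Dcn (5.12-fold), Lum (9.42-fold) and Vim (2.03-fold), and of 15 endothelial markers 1 rose, Pecam1 (2.54-fold). Without KO replicate 1 Dcn was 2.60-fold and Lum 3.08-fold higher, and without flox replicate 2 they were 7.73-fold and 18.5-fold higher. Adjusted over the list alone, these counts were 5, 2, 2, 3 and 1. Among 10 adipocyte genes 1 fell, Cidec (1.33-fold), also adjusted over the list alone. None of 17 macrophage and dendritic cell, 13 smooth muscle, 13 neuron and glia or 7 erythroid markers was listed. In limma 1, 1, 1, 0 and 1 members of these 5 groups passed, and 5, 2, 2, 2 and 1 had an unadjusted p under 0.05. On recovered reads edgeR called 2, 0, 2, 1 and 1 and DESeq2 3, 2, 2, 3 and 1.

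The score of the 13 listed non-epithelial markers was 0.648 ± 0.684 in KO (SD, n = 7) and -0.504 ± 0.432 in flox (SD, n = 9), and these markers had been selected on the same libraries. It ranged from -0.375 to 1.56 in KO and from -0.930 to 0.407 in flox, and was highest in KO replicate 1. With this score as a covariate, the median log2 difference of the lymphocyte markers was -0.13 and that of the fibroblast markers -0.73, while that of the 2 mast cell markers went from 1.10 to 1.58. The lymphocyte median was 0.91 in limma, 0.34 with quantile normalisation and 0.32 after removal of the GC trend, or 0.45 with library means kept.

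The 10 largest rises were Slc22a7, Dcn, Cxcr4, Mt1, Timp2, Mef2c, Pou2af1, Klhl6, Fcrla and Ifi209. Slc22a7 (17:46432183 to 46438457), an organic anion transporter, stood apart. It had 1110 reads over the 7 KO libraries and 3 reads over the 9 flox libraries, a ratio of 432 (95% exact interval 147 to 2097, counting error only). Without flox replicate 7 the fold of its means went from 460 to 1162. Of the other rises, the chemokine receptor Cxcr4 rose 4.86-fold, the transcription factor Mef2c 3.80-fold, and Klhl6 and Fcrla, which B cells express, 3.45-fold and 3.34-fold. Timp2, an inhibitor of matrix proteases, rose 3.86-fold, and was 1.92-fold higher without KO replicate 1. Ifi209 rose 3.09-fold. Without flox replicate 2 Mef2c was 6.72-fold and Fcrla 5.34-fold higher. Dcn, Cxcr4, Timp2, Mef2c, Klhl6 and Fcrla did not pass limma, and their log2 differences with the non-epithelial covariate were -1.03, -0.69, -0.35, -0.92, -0.65 and -0.85. Pou2af1 and Ifi209 passed limma (adjusted p = 0.0499 and 0.0397) but turned to -0.40 and -0.25 with that covariate (adjusted p = 1 in limma), so 8 of the 10 turned, and Dcn and Pou2af1 are themselves part of the score.

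The 10 largest falls were all digestive enzymes of the exocrine pancreas, among them Cel, Pnlip, Prss2, Cela3b, Amy2a1, Cela2a, Cpb1, Cpa1 and Ctrb1. Of 19 genes on the stomach and pancreas list 10 were listed, all lower in KO, and 10 were lower when adjusted over the list alone. Ctrb1, chymotrypsinogen, was at 4752 ± 8853 normalised counts in flox (SD, n = 9) and 60.6 ± 109 in KO (SD, n = 7). Without flox replicate 10 its fold went from 78.4 to 31.8, and without KO replicate 7 it went to 231. Cela1 was 11.8-fold lower in KO, and 6.31-fold without flox replicate 10. Amy2a1 has near-identical copies, so its own value is uncertain. The sum of 7 of these transcripts was 4098 to 87710 normalised counts in flox replicates 4, 6, 7, 9 and 10, and 10.4 to 47.6 in the other 4 flox libraries. In KO it ranged from 7.66 to 805. The difference in the pancreatic score did not pass an exact permutation test (p = 0.0630). None of the 10 list members passed limma and 3 had an unadjusted p under 0.05, while 6 passed edgeR and 10 passed DESeq2 on recovered reads. Without the 5 flox libraries the median log2 difference of the 10 was 0.93.

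**Figure D3:**
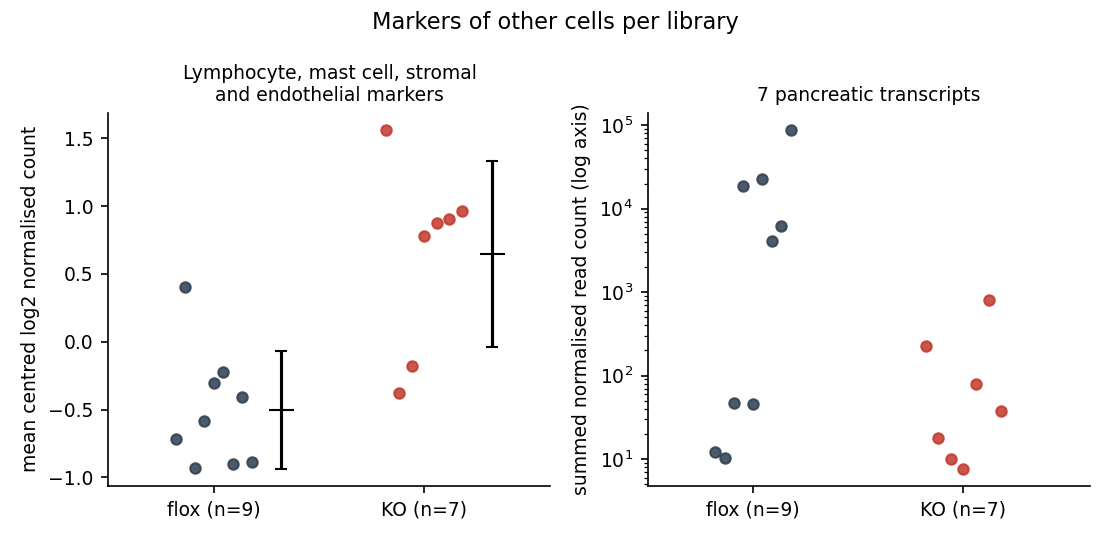
Left, the non-epithelial marker score per library (mean centred log2 normalised count of 13 markers), with the group mean and SD beside the points. Right, the summed normalised counts of 7 pancreatic transcripts per library on a log axis, where 5 of 9 flox libraries lie at 4098 or more and the KO libraries lie at 805 or less.

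Listed genes differed by GC content and abundance. The genes higher in KO had a median GC content of 45.4% and those lower in KO 54.7%. The listed genes were ordered by GC content and divided into 10 bins. In the lowest bin 231 of 244 listed genes were higher in KO, and in the highest bin 19 of 244. The genes higher in KO had a median of 73.4 normalised counts over all libraries, against 1204 for the lower genes. The correlation across genes of GC content with a library's deviation from the gene means was -0.419 to -0.0819 in KO and -0.00855 to 0.363 in flox, and genes are not independent replicates. After removal of a quadratic GC trend from each library, 428 listed genes passed limma, 72 higher and 356 lower, and the median log2 difference moved by -0.13. With the library means kept 374 passed, 109 higher and 265 lower, and the median moved by 0.01. CT010467.1 (17:39846353 to 39848827), annotated as ribosomal RNA and chosen after its values were seen, was 2.67-fold lower in KO in these poly-T libraries.

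**Figure D4:**
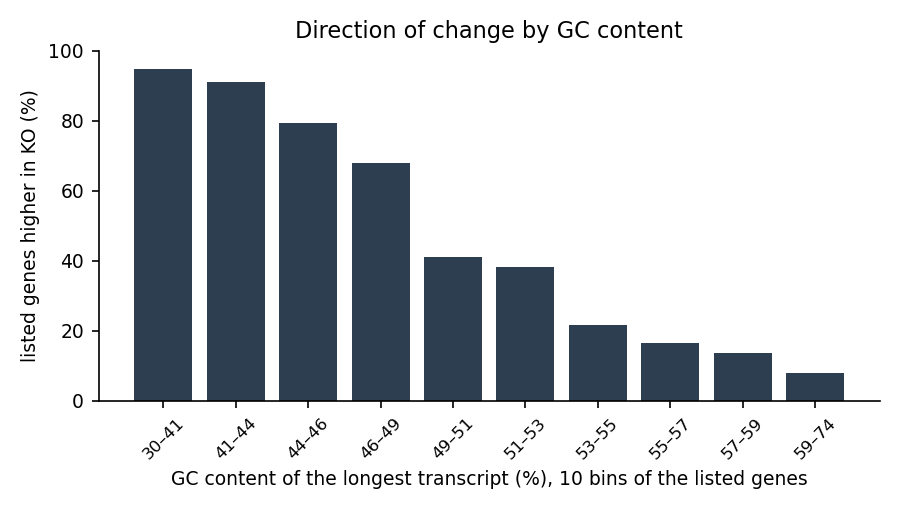
Share of listed genes higher in KO (%, bars from 0) in 10 bins of the 2437 listed genes by GC content of the longest transcript (%). The share falls from 94.7% in the lowest bin to 7.79% in the highest bin.

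Some genes on chromosome 17 separated the groups, although Ephb4 lies on chromosome 5, and the genes of this paragraph other than Slc22a7 were chosen after their values were seen. H2-T23 (17:36029773 to 36032855), a nonclassical MHC class I gene, was 2.52-fold lower in KO, at 3288 ± 632 (SD, n = 7) against 8300 ± 1472 (SD, n = 9). H2-T22 and Gm8909 were 2.18-fold and 2.34-fold lower, and H2-T10 was 3.23-fold higher. Of the listed genes on chromosome 17, 28 of 163 (17.2%) had no overlap between the groups, against 6.55% of listed genes elsewhere (Fisher's exact test, adjusted p = 0.000217 over 20 chromosomes). Chance gives 0.0175% for a gene that was not selected. The Fisher's exact test counts genes, and neighbouring genes can vary together, so its p does not measure variation between mice. Within 17:36029773 to 36190287, 10 of 12 listed genes were lower, 2 higher, and 9 had no overlap. Most of these belong to one family of MHC class I genes, among which reads can be hard to assign, so their single values are uncertain. Without this region 19 of 151 listed genes of the chromosome had no overlap (12.6%, Fisher's exact test, adjusted p = 0.157 over 20 chromosomes), among them Plin3. H2-T23, H2-T22, H2-T10, Gm8909 and Slc22a7 were the 5 genes that passed in all 31 settings of limma.

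**Figure D5:**
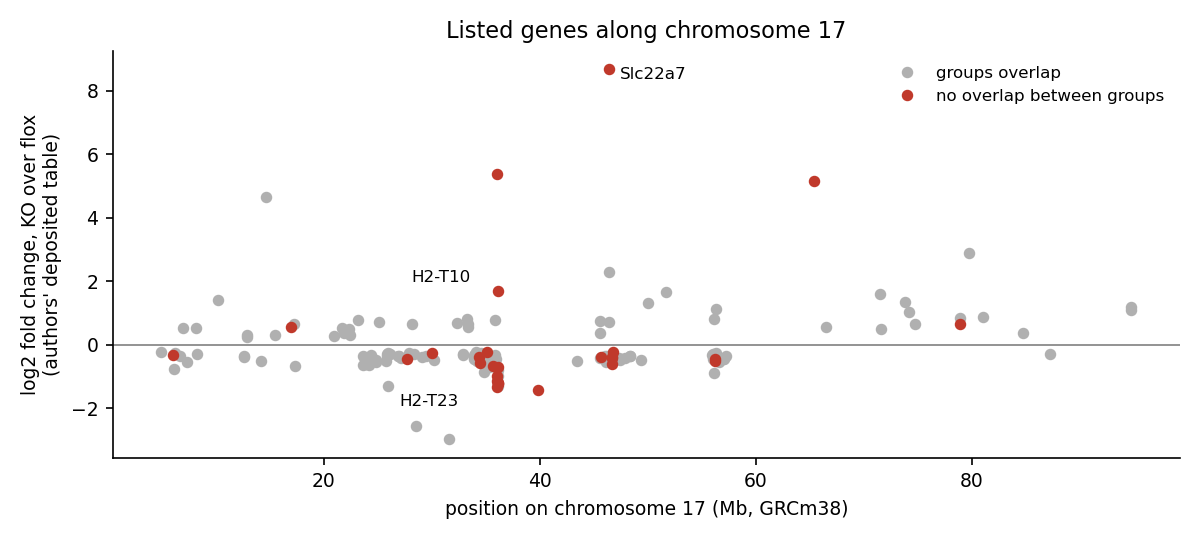
Log2 fold change of KO over flox in the authors' deposited table for the 163 listed genes along chromosome 17 (Mb, GRCm38), with red points for the 28 genes whose flox and KO libraries do not overlap. Of the 12 listed genes near 36 Mb, 10 lie below 0 and 2 above it.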

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

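The tests of explanations in this part were chosen only after the results were seen. In 194 groups of 7 or 9 libraries, 11 values stood apart from the rest of their group in log2 normalised counts, close to the 1 in 20 that chance flags. Each is given in normalised counts. In KO replicate 1 these were Ephb4 at 84.7, Timp2 at 398 and Vil1 at 36391. In KO replicate 2 Acadvl stood at 2118, and in KO replicate 7 Amy2a1 stood at 59.4. In flox replicate 2 Mylip stood at 62.4 and Tcf7 at 122, and in flox replicate 4 Khk stood at 18244 and Ftl1 at 15662. In flox replicate 9 Aurka stood at 126, and in flox replicate 10 Cd4 stood at 13.2.

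The pancreatic transcripts were high in 5 of the 9 flox libraries. Genotype alone is argued against by 4 flox libraries within the KO range. In the 5 libraries each of the 7 transcripts kept nearly its share of their sum, with a largest ratio between libraries of 1.68, as 1 source with a fixed mixture would give. A candidate source is pancreatic tissue collected with the duodenum, and the limits of 1000 summed counts for a library and 3 for the ratio were set after seeing the data. Expression of these genes by the duodenum itself in some mice was not tested.

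The lower fat genes and higher proliferation genes were set against GC content and other cells. With the GC trend of each library removed and its mean kept, the genotype difference of the fat uptake score went from -0.50 ± 0.09 to -0.43 ± 0.08 (SE). That of the oxidation score went from -0.43 ± 0.07 to -0.38 ± 0.07. By the rule used, these values argue against GC bias as the whole cause for these genes. That rule was changed after its results had been seen, and by the former rule GC bias and genotype could not be told apart. In the same setting limma called only 6 and 5 members against 10 and 8 before (4 and 3 of them the same). The members had been selected as lower on these same libraries and the trend was fitted over listed genes only, so GC bias is not excluded. The proliferation score went from 0.90 ± 0.25 to 0.74 ± 0.24, but limma in the same setting called 2 members against 8 before as the differences shrank (12 of 14 at an unadjusted p under 0.05), so GC bias and genotype cannot be told apart there. With the non-epithelial score in the model the differences of the 3 scores were -0.36 ± 0.12, -0.29 ± 0.09 and 0.63 ± 0.38 and limma called 0 members of each list (6, 4 and 2 members at an unadjusted p under 0.05), so non-epithelial cells and genotype cannot be told apart, because the score followed the genotype and its markers and the list members had been selected on these same libraries. An effect of Ephb4 loss on the balance of mature and cycling epithelium stays open.

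On chromosome 17 outside the H2-T region, 12.6% of listed genes had no overlap between the groups, against 6.55% elsewhere (Fisher's exact test, p = 0.00784, adjusted p = 0.157 over 20 chromosomes). The 9 genes without overlap inside the region are neighbours and drew attention to it. The excess outside it did not pass the adjustment over all chromosomes, and the test counts genes rather than mice. Inherited sequence variants or an insertion linked to the genotype therefore cannot be told apart from other causes. Reads exchanged only among the listed H2-T genes would keep their sum equal. The sum over the listed genes of the region was 47.3% of flox in KO (exact permutation p = 8.74e-05, the smallest possible). This argues against such exchange as the whole cause. The 12 genes had been selected as different on these libraries, 10 of them as lower, so the p is no separate support. Exchange with unlisted paralogs was not tested. Regulation of these genes by EphB4 stays open.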

How the results depend on the processing

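The covariates, the removal of GC trends, the choice of libraries by pancreatic transcripts, edgeR and the count models without KO replicates 1 and 3 were chosen after seeing the data; the other settings were planned. Each value is a count of listed genes, so none speaks of unlisted genes, and the cause of a change was not tested unless stated. The authors listed 2438 genes. On recovered reads DESeq2 called 2233 and edgeR 1443, and without KO replicates 1 and 3 they called 1218 and 418, with fewer samples. The DESeq2 run on all 16 libraries nearly repeats the authors' selection. limma without a filter called 1327, and 437 listed genes had an absolute log2 fold change of at least 1. Of the 1269 genes of the main limma check, with 67 gene list members among them, 118 had an absolute log2 difference of at least 1. Quantile normalisation left 357 genes (192 higher, 165 lower) and 12 list members, moved the median log2 difference by 0.10 and turned the sign of 476 genes. It was run over genes selected as changed, so these losses and turns follow in part from the method. TMM scaling left 39 list members. The pancreatic covariate left 466 genes and 35 members, the non-epithelial covariate 7 genes and 1 member, and leaving out the flox libraries with pancreatic transcripts 11 genes and 2 members, from 4 flox libraries against 7. Removal of the GC trend left 428 genes and 30 members, 374 and 27 with the library means kept, and with the replicate block as well 59 and 5. Leaving out 1 library at a time gave 518 (KO replicate 7) to 1458 (KO replicate 2) genes and 28 to 78 members.

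The labels do not say whether the replicate numbers pair the samples. Correlations of same-numbered libraries over the listed genes were -0.380, -0.431, 0.371, -0.0847, 0.103 and 0.245. Only 1 of the 6 KO libraries correlated best with its own number. These values show no general pairing but cannot exclude it, because the genes had been selected by genotype. With the replicate block in 12 libraries 9 genes and 1 list member passed, against 355 and 32 in the same 12 without it. Ephb4 had a log2 difference of -2.30 with the block (adjusted p = 0.0661 in limma). It passed in the other 29 of 30 alternatives, at -3.10 to -2.02, and at -2.73 to -2.40 with 1 library left out.

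The median log2 difference of 10 lists stayed within 1 SD of the main value in 285 of 300 list and setting pairs. In 11 pairs it changed by more with its sign kept, as when the fat uptake median shrank from -0.48 to -0.09 with quantile normalisation. In 4 pairs it reversed. This SD is that of the list score between libraries, in the group where it was larger, and is wide for some lists: the pancreas median went from -3.92 to -0.02 with its own score as covariate, and the enteroendocrine median from -0.47 to -0.18 with the non-epithelial one, both within it. With the non-epithelial covariate the lymphocyte median was -0.13 and the fibroblast median -0.73, the pancreas median was 0.93 without the 5 flox libraries, and the junction median 0.0596 with quantile normalisation. The first principal component held 49.8% of the variance, and 50.7% over the 500 most variable genes. No set test with either correlation was run, since the table held only selected genes. Of 100 splits of the libraries 1, the real one, gave as many genes as 1269, and the highest of the others gave 2, but the authors chose these genes by the real split, so this count cannot exclude chance. Unknown total depth leaves the fractions of all reads and the unlisted genes out of reach.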

Other observations

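The families in this part were chosen by gene symbol after the data were seen, and 9 families were compared with Fisher's exact test against the other listed genes. Genes of a family can vary together, and all had been selected on these same libraries. The p-values therefore describe directions among listed genes only. They do not measure variation between mice and are no separate support for a family. Cytosolic ribosomal protein genes were mostly higher in KO, 16 of 17 listed (adjusted p = 0.000163). Rps12 rose 2.08-fold, from 1412 ± 372 (SD, n = 9) to 2942 ± 488 (SD, n = 7) normalised counts. Genes of splicing and RNA binding proteins were higher in 21 of 24 (adjusted p = 0.000146), with Srsf2, Srsf10 and Luc7l3 1.31-fold, 1.35-fold and 1.29-fold higher. Kinesin, centromere and condensin genes were higher in 18 of 21 (adjusted p = 0.000836), and zinc finger genes named Zfp in 45 of 55 (adjusted p = 1.26e-06). After removal of the GC trend the median log2 difference was 0.37 for the ribosomal and 0.46 for the kinesin family, and -0.19 for the splicing and -0.15 for the zinc finger family. This removal also dropped the library means, which shifts all genes down alike. The median log2 difference of the listed genes moved by -0.13, against 0.01 with the means kept. The signs of the splicing and zinc finger medians are therefore uncertain.

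Solute carrier genes were mostly lower in KO, 50 of 61 listed (adjusted p = 1.30e-05), and genes of acyl-CoA enzymes in 16 of 17 (adjusted p = 0.000642), by the same test with the same limits. After removal of the GC trend their median log2 differences were -0.31 and -0.45, against -0.36 and -0.39 before. The library means were dropped here too, so part of these remaining falls is the shift common to all genes. Rab GTPases (9 of 11 lower, adjusted p = 0.0893), glycosyltransferases (7 of 10 lower, adjusted p = 0.394) and Eif translation factors (5 of 11 higher, adjusted p = 1) did not pass. Among single genes chosen after their values were seen, Pdzk1, a scaffold of brush border transporters, fell 1.75-fold and Enpp7, the alkaline sphingomyelinase of the intestine, fell 2.62-fold. The butyrophilin-like genes Btnl1 and Btnl6, which act on intraepithelial lymphocytes, fell 1.31-fold and 1.5-fold, and both are among the 28 listed genes of chromosome 17 without overlap between the groups.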
